A study of Mus musculus with 16 samples.

How the data were processed

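Inguinal white adipose tissue of 16 male mice was profiled by poly-A RNA sequencing, per the labels' protocols with a stranded mRNA kit, paired reads of 150 bases and RNA integrity numbers above 7. Reads were aligned with STAR 2.7.3a to GRCm38, per the submitters' processing notes. The authors counted read pairs per gene with featureCounts 2.0.3 against the Ensembl 102 annotation and without using strand, per the file headers, so the deposited counts are whole numbers and are not normalised. Because strand was not used, reads of a gene and of an overlapping or antisense partner cannot be told apart, and near-identical gene copies are uncertain. The authors also deposited, per the file headers, a table of KO against WT for each diet with log2 fold changes. The p-values in the same deposited tables are the authors' DESeq2 results, per the submitters' processing notes, with no version given in the sources used here. Both tables were used only for the values credited to them. All count columns were mapped to samples by the animal code in their names.

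Of 55487 genes, 55141 took their symbol from the reference table, 13 from the authors' tables, and 333 had none. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes with too few counts were removed with filterByExpr, which left 16549. Factors were computed by TMM. A quasi-likelihood model (glmQLFit, robust) with the 4 group means was fitted to all 16 libraries together, and glmQLFTest gave 6 comparisons: KO against WT on chow, on HFD and over both diets, HFD against chow in WT and in KO, and the interaction. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05 and no minimum fold change. CPM values use TMM factors, means are given with the SD, and log2 CPM has a prior count of 2. Intervals of log2 fold changes are 95% intervals. Counting intervals of ratios cover counting error only. Library totals ran from 13824404 to 16909361 read pairs, so 1 CPM stands for 14 to 17 counts, and named genes with 1 to 3 counts over a group are given with the counting interval of their ratio.

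The design, the alternatives, 31 lists of genes and the rule for genes named in the text were fixed before the data were examined. The rule names Kmo in each comparison and the 10 largest increases and decreases among called genes without overlap between the groups and with a mean CPM of at least 1 in a group, leaving out predicted genes. For reported lists it takes up to 4 members, first the called ones by adjusted p, otherwise the most abundant, and where fewer than 5 genes are called the 5 with the smallest p. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. A list's score in a library is the mean log2 CPM of its members. The lymphoid score joins the T cell and B cell lists. Which lists and how many of their members are described was chosen after the results were seen. Some members that the rule would name are not reported here.

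The count model was tested on simulated data with 200 changed genes among 16549, 50 at each fold. For KO against WT on chow, 52% of genes changed 2-fold and 78% of those changed 4-fold were recovered, with 4 false calls. For KO against WT on HFD these were 38% and 66% with 2 false calls. For HFD against chow they were 54% and 66% with 0 false calls in WT, and 46% and 74% with 7 false calls in KO. Of genes changed 1.5-fold between genotypes, 12% were recovered on each diet. The simulated counts lacked the shared lymphoid and muscle differences of the real libraries. In them 4.73% of unchanged genes on chow and 4.75% on HFD had an unadjusted p under 0.05 (edgeR). In the real comparisons 1% and 1.14% of genes did, so recovery in the real data may differ. No pair of libraries had counts within sampling noise of each other (lowest chi-square per gene 12.7).

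Alternatives were relative log expression and upper-quartile factors, DESeq2, limma-voom with quality weights, no filter, a filter of CPM 1 in 4 libraries, a minimum log2 fold change of 1, a threshold of 0.10, the replicate number as a block, 1 surrogate variable, lymphoid or muscle scores as covariates, only the 8 libraries of a comparison, and leaving out each library in turn. Added after seeing the data were both scores together, a term for libraries from a single lane, only the libraries merged over lanes, and only the 10 libraries with a lymphoid score under 4. Per the file headers, 12 libraries were merged over lanes; WT chow replicate 2 and WT HFD replicates 3 and 4 came from lane 6 alone and KO HFD replicate 1 from lane 4.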

Results

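RNA of the inguinal white adipose tissue, a subcutaneous fat depot of the groin, was sequenced from male mice lacking Kmo in the whole body and from wild-type (WT) littermates. Kmo encodes kynurenine 3-monooxygenase, the enzyme of the kynurenine branch of tryptophan breakdown that turns kynurenine into 3-hydroxykynurenine. The animals were 6 to 7 months old and were fed chow or a high-fat diet (HFD), which gave 4 groups of 4 animals: WT chow, knockout (KO) chow, WT HFD and KO HFD. Each of the 16 libraries came from a separate animal. Libraries held 14680422 to 15713868 counted read pairs in WT chow, 15276739 to 15903991 in KO chow, 15094130 to 16701388 in WT HFD and 13824404 to 16909361 in KO HFD. Of 55487 genes in the count table, 16549 were tested. Scd1, a desaturase of lipid synthesis, took the largest share of counts in every library.

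Kmo itself was measured first. The gene (ENSMUSG00000039783) lies on chromosome 1 from 175620381 to 175662116 in GRCm38, and the counts cover all of its exons together. WT chow libraries held 117, 236, 40 and 298 counts of Kmo and KO chow libraries 2, 8, 3 and 3 counts. WT HFD libraries held 42, 215, 69 and 90 counts and KO HFD libraries 1, 2, 2 and 1 counts. Mean expression was 11 ± 7.27 CPM (counts scaled to library size; SD, n = 4) in WT chow, 0.259 ± 0.191 in KO chow, 6.66 ± 4.87 in WT HFD and 0.0992 ± 0.0337 in KO HFD. Every KO library lay below every WT library, so the genotype in all 16 labels fitted the level of the targeted gene. Kmo does not check the diet in the labels. Counts over the whole gene do not show which exons were deleted.

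**Figure D1:**
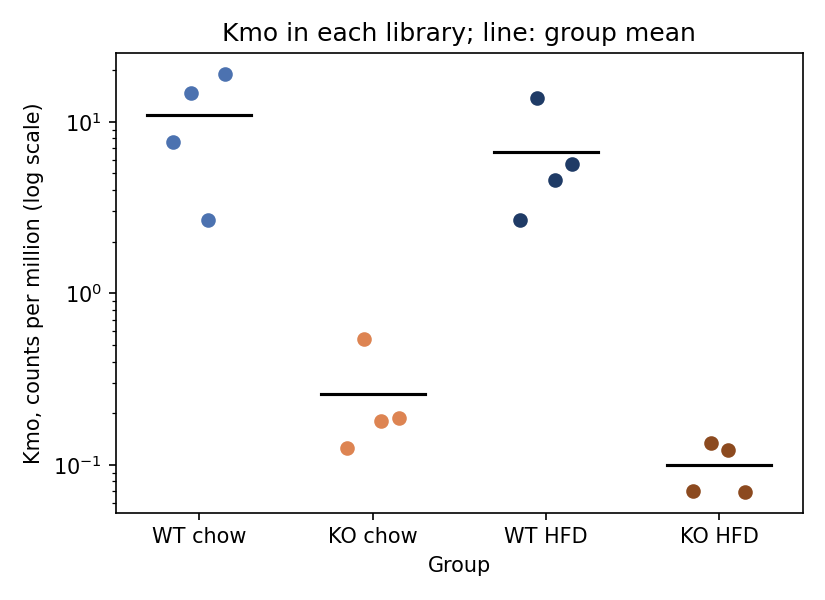
Kmo expression of each library in CPM on a log axis, by group (4 libraries each), with a line at the group mean. All KO libraries sit at or below 0.543 CPM, and all WT libraries at or above 2.66 CPM.

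The comparison of KO with WT on chow asked what loss of Kmo changes in lean animals. Kmo was lower in KO by a log2 fold change of −5.38 (SE 0.70, edgeR quasi-likelihood test, adjusted p = 0.0253), and no other gene passed the threshold. The genes next in rank were Pkp4 (plakophilin 4, a junction protein), at 57.7 ± 8.94 CPM in KO and 43.1 ± 1.92 in WT, Ripply3, Mlana (a melanocyte gene), Cers6 (ceramide synthase 6) and Impa1 (inositol monophosphatase). Their log2 fold changes were 0.42, 0.67, −1.39, −0.42 and 0.31, with edgeR adjusted p of 1 for each. Only 166 genes (1% of those tested) had an unadjusted p under 0.05, and 92 genes (0.556%) had no overlap between the groups' libraries, where chance gives 2.86%. DESeq2 also called 1 gene, and limma-voom called 0 genes with 78 at an unadjusted p under 0.05. The authors' deposited table for this comparison gave Kmo a shrunken log2 fold change of −5.26 with a DESeq2 adjusted p of 2.19e-12, and held 1 gene under 0.05. The single edgeR call was lost when any of 12 libraries was left out: WT chow replicates 1, 2 and 4, all 4 KO chow, WT HFD replicate 4 and all 4 KO HFD libraries. Kmo then had log2 fold changes of −5.99 to −4.98 and an adjusted p of up to 0.267, the highest without KO chow replicate 3.

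Among the fixed gene lists on chow, fatty acid oxidation genes had a log2 fold change above 0 in 25 of 26 members (median 0.19), with Acadm, the medium-chain acyl-CoA dehydrogenase, at 0.32. Nuclear-encoded oxidative phosphorylation genes were above 0 in 29 of 32 members (median 0.16, Atp5b 0.15) and thermogenic adipocyte genes in 16 of 20 (median 0.32, Cidea 0.40). Erythrocyte (5 of 5) and endothelial genes (14 of 16) lay above 0 as well. Skeletal muscle genes were below 0 in KO (median −1.60, Myh4 −2.10 and Acta1 −1.68), as were immediate early and heat shock genes (median −0.26), de novo lipogenesis genes (median −0.09) and lipid-associated macrophage genes (median −0.10). No member of these 9 lists passed the gene-level threshold, over all genes or adjusted over the list alone. The mean log2 CPM of skeletal muscle genes was 2.82 ± 2.68 in KO chow and 3.90 ± 2.51 in WT chow libraries (SD, n = 4), so its spread between animals exceeded the difference. Camera with its preset correlation called these 9 of 31 lists, from an adjusted p of 5.18e-12 for fatty acid oxidation to 0.0378 for lipid-associated macrophage genes. With an estimated correlation none was called, and the lowest adjusted p = 0.603 with an estimated correlation was that of fatty acid oxidation and others. Directions turned without KO chow replicate 2 (oxidative phosphorylation, mean −0.03), KO chow replicate 4 (lipogenesis, 0.06) or WT chow replicate 3 (skeletal muscle, 0.58, and immediate early genes, 0.07). In the kynurenine pathway and NAD synthesis list, Kmo was the only called member of 19 (1 adjusted over the list alone), and Nampt, the rate-limiting enzyme of NAD salvage, stood at 0.22 (edgeR adjusted p = 1). That list had a mean of −0.29 and a median of −0.02, and camera gave it an adjusted p of 0.540 (0.806 with an estimated correlation).

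KO and WT were compared on HFD to ask the same of diet-fed animals. Kmo was lower in KO by a log2 fold change of −5.95 (SE 0.78, edgeR adjusted p = 0.0262). From 6 counts in KO HFD against 416 in WT HFD, WT had 66.5 times the Kmo level of KO (counting interval 30.3 to 182). No other gene passed. Next in rank were Dpp7 (a lysosomal dipeptidyl peptidase, 23.0 ± 1.28 CPM in KO and 28.2 ± 0.830 in WT), Muc13, Capn11 and Prcd, with log2 fold changes of −0.29, −1.94, 5.63 and −0.82 and edgeR adjusted p of 1. With them ranked a gene identifier that shares the symbol Aldoa (ENSMUSG00000114515), at 0.458 ± 0.180 CPM in KO and 1.49 ± 1.05 in WT. It lies next to the main Aldoa gene on chromosome 7, and a value at so few counts is uncertain. Capn11, a calpain, had 121 counts over the KO HFD libraries and 2 over the WT HFD libraries, a ratio of 63.1 (counting interval 17.1 to 527). The authors' deposited table gave Capn11 a shrunken log2 fold change of 5.35 with a DESeq2 adjusted p of 0.0516. The same deposited table gave Kmo a shrunken value of −5.87 with a DESeq2 adjusted p of 3.65e-11, and held 1 gene under 0.05. At an unadjusted p under 0.05 there were 188 genes by edgeR, while 235 genes (1.42%) had no overlap between the groups, where chance gives 2.86%. DESeq2 called 1 gene, and limma-voom 0 genes with 912 at an unadjusted p under 0.05. The edgeR call was lost without WT chow replicate 1, KO chow replicate 3 or 4, WT HFD replicate 4 or any of the 4 KO HFD libraries, with Kmo at −6.10 to −5.83 and an adjusted p of up to 0.273 (without KO HFD replicate 4).

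On HFD the lists below 0 in KO were skeletal muscle (17 of 17 members, median −1.87, Myh4 −2.34, Acta1 −1.83), lipid-associated macrophage genes (median −0.26, Ctsd, which encodes cathepsin D, −0.32), macrophage genes (median −0.26, C1qb −0.43), interferon response (median −0.23, Gbp2 −0.26), inflammatory cytokines and receptors (median −0.24), extracellular matrix (median −0.09), endoplasmic reticulum stress and amino acid response (median −0.07) and hypoxia response (median −0.09, Aldoa −0.08). Lists above 0 were mitochondrially encoded transcripts (13 of 13, median 0.25, mt-Cytb 0.19), insulin signalling and glucose use (median 0.11), de novo lipogenesis (median 0.18, Scd1 0.35 and Fasn 0.33), triglyceride storage and lipolysis (median 0.07) and adipocyte identity and adipokines (median 0.08). No member passed at the gene level, over all genes or adjusted over the list alone. Camera called these 13 lists with adjusted p from 1.52e-09 (skeletal muscle) to 0.0496 (adipocyte identity). None was called with an estimated correlation, where the lowest adjusted p = 0.424 with an estimated correlation. The skeletal muscle score was 2.57 ± 1.55 in KO HFD and 4.24 ± 1.79 in WT HFD libraries (SD, n = 4). Camera directions turned with that score as a covariate for extracellular matrix (mean 0.0269) and skeletal muscle (0.0678), with both scores for the same lists (−0.00539 and 0.0472), and in merged libraries for endoplasmic reticulum stress genes (−0.0143). Without WT HFD replicate 2 the inflammatory list had a mean of 0.05. The kynurenine pathway list again held Kmo as its only called member of 19 (1 adjusted over the list alone), with a camera adjusted p of 0.411 (0.816 with an estimated correlation), a median of 0.05 and a mean of −0.23.

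Over both diets together, 8 KO libraries against 8 WT libraries, Kmo was again the only gene past the threshold, with a log2 fold change of −5.66 (SE 0.52, edgeR adjusted p = 3.12e-04) and means of 0.179 ± 0.153 CPM in KO and 8.83 ± 6.18 in WT. This call held without any single library. Ppfibp2, Lrrc15, Cbx3 and Atp6v1c2 ranked next, at −0.41, 0.89, 0.21 and 0.72 with edgeR adjusted p of 1, together with the low-count identifier ENSMUSG00000114515 of Aldoa at −1.08. Unadjusted p values under 0.05 numbered 165. DESeq2 called 1 gene, and limma-voom called 0 genes with 261 at an unadjusted p under 0.05. The median half-width of the 95% interval of a gene's log2 fold change was 0.31 here and 0.43 within each diet, so smaller differences were not detectable in most genes. Larger differences could be missed too, because calls were adjusted over all genes. Of simulated 1.5-fold changes (0.585 on the log2 scale), 12% were recovered on chow and 12% on HFD. Camera called 13 lists. Thermogenic, oxidative phosphorylation, mitochondrially encoded, fatty acid oxidation, triglyceride storage, insulin signalling and endothelial genes lay above 0. Skeletal muscle, macrophage, lipid-associated macrophage, inflammatory, interferon and extracellular matrix genes lay below 0. Camera directions turned for oxidative phosphorylation without KO chow replicate 2 (mean −0.0214), for macrophage genes in merged libraries (1.56e-04) and for extracellular matrix with the muscle score (0.00240), with both scores (−0.0243) and in merged libraries (−0.0228). Ctsd stood at −0.20, Myh4 at −2.22 and Acta1 at −1.75, and no list member but Kmo was called, over all genes or adjusted over the list alone. None of the 13 list calls held with an estimated correlation (lowest adjusted p = 0.551 with an estimated correlation). In the kynurenine list, with Kmo the only called member of 19 (1 adjusted over the list alone), the median was 0.04, the mean −0.26 and the camera adjusted p 0.254 (0.594 with an estimated correlation).

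Whether the knockout acts differently on the 2 diets was tested as an interaction. No gene passed by edgeR, DESeq2 or limma-voom, and 187, 300 and 289 genes had an unadjusted p under 0.05. Kmo differed by −0.56 (SE 1, edgeR adjusted p = 1). Ripply3, Muc13, Fosb, H2afy2 and Serpina1d had the smallest p, with differences of −0.98, −2.65, 5.24, −0.77 and 1.76 on the log2 scale and edgeR adjusted p of 1. Fosb, an immediate early gene, stood at 5.45 log2 CPM in WT chow replicate 3 and at most at 1.24 in the other WT chow libraries. Across 16548 genes without Kmo, the knockout's log2 fold changes on chow and HFD had a Pearson correlation of 0.119 and a Spearman correlation of −0.00873, and 48.3% had the same sign; genes are not independent replicates. Camera called 7 lists in the interaction, with lower KO effects on HFD for oxidative phosphorylation, fatty acid oxidation, interferon and erythrocyte genes, and higher ones for lipogenesis, mitochondrially encoded and immediate early genes. Directions turned for oxidative phosphorylation without KO chow replicate 2 (mean 0.0153) and in merged libraries (0.103), for fatty acid oxidation in merged libraries (0.0410), and with lymphoid scores under 4 for interferon (0.0374) and mitochondrially encoded genes (−0.0150). None was called with an estimated correlation (adjusted p = 0.797 with an estimated correlation for all 7), and no member was called, over all genes or adjusted over the list alone. The kynurenine list had a camera adjusted p of 0.751 (0.905 with an estimated correlation), with a median of 0.02 and a mean of 0.05 although its camera direction was down.

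RNA of other tissues differed between animals more than between genotypes. The inguinal depot can hold a lymph node, and the mean log2 CPM of T cell and B cell genes (the lymphoid score) ran from −0.36 to 5.44. It averaged 3.08 ± 2.39 in WT chow, 2.76 ± 2.34 in KO chow, 1.31 ± 1.90 in WT HFD and 1.24 ± 2.18 in KO HFD (SD, n = 4). The score was over 4 in 2 WT chow, 2 KO chow, 1 WT HFD and 1 KO HFD libraries. Skeletal muscle genes spanned 0.47 to 6.97 on the same scale. The first principal component held 45.0% of the variance of log2 CPM.

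**Figure D2:**
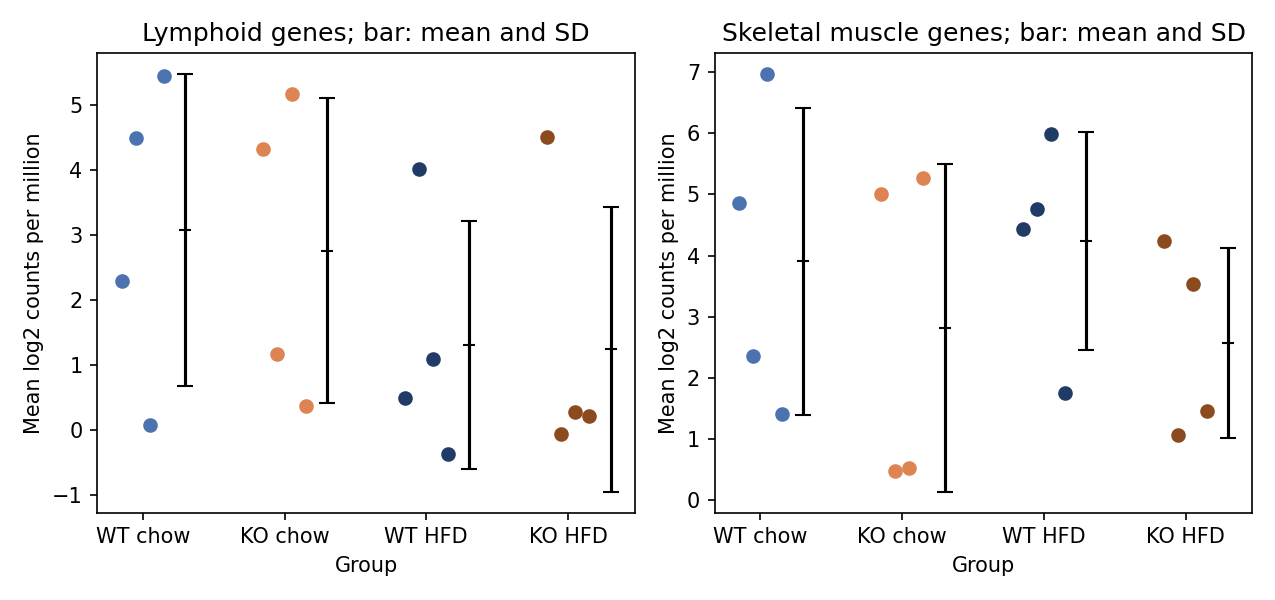
Mean log2 CPM of lymphoid genes (left) and skeletal muscle genes (right) in each library, by group, with the mean and SD of the 4 libraries beside them. Lymphoid scores run from −0.36 to 5.44, and both scores overlap between genotypes.

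HFD was compared with chow in WT animals to describe the diet's effect on this depot. The fructose transporter gene Slc2a5 fell by 7.93 on the log2 scale (SE 0.96, from 21.6 ± 13.6 to 0.0810 ± 0.0624 CPM), the uncoupling protein gene Ucp1 by 5.54 (SE 1.01, from 71.6 ± 100 to 1.54 ± 1.11 CPM) and the fatty acid elongase gene Elovl6 by 3.90 (SE 0.49, from 603 ± 179 to 40.3 ± 10 CPM). Lep, which encodes leptin, rose by 1.93 (SE 0.37, from 1247 ± 535 to 4743 ± 432 CPM). In all, 1957 genes passed the threshold, 1142 higher and 815 lower on HFD, and 1734 of them had no overlap between the groups; over all tested genes 17.4% had none, where chance gives 2.86%. With upper-quartile factors the split was 902 higher and 1031 lower. DESeq2 called 2743 genes. The other largest decreases were Slc27a2 (−4.77, a fatty acid transport protein), Cyp1a1 (−4.12, a target of the aryl hydrocarbon receptor), Ttc25 (−4.07), Aspg (−3.98, an asparaginase), Sorcs2 (−3.87), Cyp2f2 (−3.83) and Acox2 (−3.63, a peroxisomal oxidase). By a fitted fold change over a group without counts, increases were led by Gpr50, an orphan receptor related to melatonin receptors. It had no count in the 4 WT chow libraries and 3.09 ± 1.81 CPM on HFD, at least 16-fold higher against a floor of 3 counts per library. Rnase2a (5.29), Itgad (4.94, an integrin subunit of macrophages), Cacng5 (4.33), Saa3 (4.15, serum amyloid A3), Arl14epl (4.13), Mrgprg (3.80), Ubd (3.59), Dsg1b (3.53) and Tph2 (3.47, tryptophan hydroxylase 2) followed. Adjusted p of these 20 genes and Lep lay between 0.00133 and 0.0427 (edgeR). Rnase2a and Saa3 belong to families of similar genes whose reads may have been divided. Kmo did not pass (−0.72, edgeR adjusted p = 0.396).

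The number of calls fell to 923 without WT chow replicate 1, 800 without WT chow replicate 4, 1064 without WT HFD replicate 2 and 689 without WT HFD replicate 3. In WT, calls of these genes ended in at least 1 fit without a single library. The highest edgeR adjusted p were 0.0733 for Itgad, 0.0910 for Arl14epl, 0.118 for Mrgprg, 0.0679 for Dsg1b, 0.0983 for Slc27a2, 0.0577 for Bgn and 0.0512 for Sparc, each without WT chow replicate 4. They were 0.107 for Tph2, 0.0627 for Aspg and 0.0530 for Postn, each without WT HFD replicate 3. They were 0.0847 for Ighm without WT chow replicate 1 and 0.0860 for Nampt without WT HFD replicate 1. Log2 fold changes there kept their signs, for example 4.69 for Itgad, −3.20 for Slc27a2 and 3.04 for Tph2.

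By list in WT, de novo lipogenesis fell on HFD: 12 of 21 members were lower and 1 higher (14 and 1 adjusted over the list alone), with Acaca at −2.64, Acly at −2.63 and Tkt at −1.86 beside Elovl6. Camera gave an adjusted p of 2.51e-14, and the adjusted p = 0.158 with an estimated correlation. Mitochondrially encoded transcripts were lower in 10 of 13 members (13 adjusted over the list alone), mt-Nd5 at −1.10 and mt-Nd4 at −1.33 (adjusted p = 0.158 with an estimated correlation). The share of all counts from mitochondrial genes was 6.14 ± 1.45% in WT chow and 2.98 ± 0.384% in WT HFD. Thermogenic genes were lower in 8 of 20 (11 adjusted over the list alone), with Cidea at −2.53 and the fatty acid receptor Ppara at −1.65 beside Ucp1 (adjusted p = 0.303 with an estimated correlation). Circadian clock genes were lower in 11 and higher in 3 of 18 (12 and 5 adjusted over the list alone), with Ciart at −3.13, Bhlhe40 at −2.22 and Hlf at −2.18 (adjusted p = 0.0629 with an estimated correlation). Extracellular matrix genes were higher in 12 of 27 (14 adjusted over the list alone), Sparc by 1.21, Postn by 1.19 and Bgn by 0.86 (adjusted p = 0.303 with an estimated correlation). Endoplasmic reticulum stress and amino acid response genes were higher in 7 of 18 (10 adjusted over the list alone), the chaperone genes Hspa5 by 0.98, Hsp90b1 by 0.59 and Calr by 0.49 (adjusted p = 0.157 with an estimated correlation). Camera called these 6 lists. Fry, which tests only whether a list's genes move on balance in a single direction, also called them, with adjusted p from 1.87e-04 (clock) to 0.0207 (thermogenic).

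The remaining 6 camera calls in WT were oxidative phosphorylation (lower; 0 of 32 members called, 0 adjusted over the list alone), lipid-associated macrophage (higher; 1 of 22, 0 adjusted over the list alone), T cell (lower; 0 of 22, 0 adjusted over the list alone), adipose progenitor and fibroblast (higher; 3 of 21, 4 adjusted over the list alone), endothelial (higher; 2 of 16, 2 adjusted over the list alone) and cell cycle (higher; 1 of 20, 1 adjusted over the list alone). All 6 had an adjusted p = 0.828 with an estimated correlation. T cell genes had a median of −2.42 with Tcf7 at −2.98 (edgeR adjusted p = 0.256), and the lymphoid score was 3.08 ± 2.39 in WT chow and 1.31 ± 1.90 in WT HFD. Ighm, the immunoglobulin heavy chain of B cells, was higher on HFD by 0.94 (SE 0.25, edgeR adjusted p = 0.0289) and was the only called member of 21 in the B cell and lymph node list, whose median was −1.21. Ighm did not track the B cell gene Cd79a. WT HFD replicate 4 had 858 CPM of Ighm and 0.189 of Cd79a, and WT HFD replicate 2 had 1460 and 79.8. WT chow replicate 4 had 742 and 85.7. The rise of Ighm was therefore no measure of B cell RNA. No macrophage gene of 20 was called (Lyz2 0.09, Csf1r 0.45, edgeR adjusted p = 0.876 and 0.355).

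Lists without a camera call in WT held called genes in both directions, in 1 direction or none. Fatty acid oxidation had 4 of 26 higher and 1 lower (5 and 1 adjusted over the list alone), with Acaa1b at 1.21 and the mitochondrial importer Cpt1a at 1.10 against Ppara at −1.65. Adipocyte identity had 2 of 23 higher and 3 lower, Lep against the insulin-responsive glucose transporter Slc2a4 at −0.97. Kynurenine pathway and NAD synthesis had 2 of 19 higher, with the amino acid transporter subunit Slc3a2 at 1.03, and 2 lower, with Nampt at −0.65 (camera adjusted p = 0.536, 0.828 with an estimated correlation). Numbers of higher and lower members were 1 and 5 of 20 in insulin signalling, 3 and 1 of 25 in triglyceride storage, 2 and 0 of 20 in cholesterol synthesis, 0 and 1 of 7 in aryl hydrocarbon receptor targets (Cyp1a1), 1 and 0 of 22 in inflammatory cytokines (Saa3), 0 and 2 of 22 in interferon response, 2 and 2 of 17 in hypoxia response and 2 and 1 of 18 in antioxidant genes. They were 2 and 1 of 19 in immediate early genes, 1 and 0 of 11 in smooth muscle, 1 and 0 of 4 in epithelium, 0 and 1 of 10 in nerve, and 0 in skeletal muscle (17 measured) and erythrocyte genes (5 measured). Adjusted over the list alone these counts were 1 and 0 in cholesterol synthesis, 0 and 3 in interferon response, 3 and 2 in hypoxia response and 2 and 2 in antioxidant genes, and equal to those given in the others.

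In KO animals the same comparison gave 2071 genes, 1205 higher and 866 lower on HFD (919 and 1113 with upper-quartile factors, and 2810 by DESeq2), of which 1741 had no overlap between the groups. Slc2a5 fell by 7.00 on the log2 scale (SE 0.90, from 20.4 ± 13.1 to 0.156 ± 0.121 CPM), Ucp1 by 6.72 (SE 1.08, from 105 ± 63.2 to 0.985 ± 0.122 CPM) and Elovl6 by 3.91 (SE 0.49). Lep rose by 1.88 (SE 0.37, from 1292 ± 752 to 4763 ± 1491 CPM). Further decreases were Atp4b (−5.40), Aspg (−5.19), Adprhl1 (−4.77), Fabp3 (−4.62, a fatty acid binding protein), Fer1l6 (−4.50), Sorcs2 (−4.15) and Hpcal4 (−3.98). Increases were Cacng5 (5.48), Rnase2a (5.05), Chrm4 (4.96, a muscarinic receptor), Gpr50 (3.78), Duox2 (3.58, a dual oxidase), Ina (3.49), Sult4a1 (3.02), the imprinted genes Mest (2.89) and Zim1 (2.85), and the clock gene Arntl (2.80). Adjusted p of these 20 genes and Lep lay between 0.00159 and 0.0445 (edgeR). Some rest on few counts: Cacng5 had 64 against 1 (ratio 67.7, counting interval 11.7 to 2715), Atp4b 65 against 1 (61.5, 10.6 to 2464) and Chrm4 105 against 3 (37.0, 12.3 to 182). Kmo did not pass (−1.29, edgeR adjusted p = 0.364).

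The count of calls in KO was 947 without KO chow replicate 2, 785 without KO chow replicate 3, 745 without KO HFD replicate 2, 824 without KO HFD replicate 3 and 1062 without KO HFD replicate 4. Genes whose call ended in at least 1 such fit had their highest edgeR adjusted p as follows. Without KO chow replicate 3 it was 0.118 for Ina, 0.0817 for Gpr50, 0.0788 for Mest, 0.0503 for Sult4a1 and 0.0517 for Bgn. It was 0.0728 for Duox2 without KO HFD replicate 3, 0.0953 for Hpcal4 and 0.0629 for Cox6c without KO HFD replicate 2, and 0.0710 for Col6a2 without KO chow replicate 2.

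By list in KO, de novo lipogenesis had 9 of 21 members lower and 1 higher (10 and 1 adjusted over the list alone; Acaca −2.40, Tkt −1.61), mitochondrially encoded transcripts 8 of 13 lower (9 adjusted over the list alone; mt-Cytb −1.21), and thermogenic genes 8 of 20 lower (9 adjusted over the list alone; Cidea −2.81). Extracellular matrix had 10 of 27 higher (16 adjusted over the list alone; Col6a2 1.10, Bgn 0.90). All 4 had an adjusted p = 0.348 with an estimated correlation. Clock genes were lower in 11 and higher in 4 of 18 (12 and 5 adjusted over the list alone; Ciart −3.38, Bhlhe40 −2.19; adjusted p = 0.142 with an estimated correlation). Endoplasmic reticulum stress and amino acid response genes were higher in 6 and lower in 1 of 18 (7 and 1 adjusted over the list alone), with Hspa5 at 0.76 and the serine synthesis gene Psat1 at 0.85 (adjusted p = 0.348 with an estimated correlation). Oxidative phosphorylation was lower in 5 of 32 members (16 adjusted over the list alone; Cox6c −0.78; adjusted p = 0.756 with an estimated correlation). Interferon response was lower in 4 of 22 (5 adjusted over the list alone; Xaf1 −0.59; adjusted p = 0.583 with an estimated correlation). The mitochondrial share was 6.66 ± 1.53% in KO chow and 3.19 ± 0.432% in KO HFD.

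Camera called 12 lists in KO, these 8 and T cell (lower; 0 of 22, 0 adjusted over the list alone), cholesterol synthesis (higher; 3 of 20 higher and 1 lower, also adjusted over the list alone), adipose progenitor (higher; 2 of 21, 2 adjusted over the list alone) and cell cycle (higher; 1 of 20, 1 adjusted over the list alone), each with an adjusted p = 0.789 with an estimated correlation. The lymphoid score was 2.76 ± 2.34 in KO chow and 1.24 ± 2.18 in KO HFD. Ighm was higher by 1.32 (SE 0.26, edgeR adjusted p = 0.00729), again the only called member of 21 in its list. Cyp1a1 was lower on HFD (log2 fold change −3.81) and Slc3a2 was higher by 0.94. The kynurenine list held 2 higher and 2 lower of 19 (camera adjusted p = 0.398, 0.789 with an estimated correlation).

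The diet effect was compared between genotypes. Of the genes called in each, 1226 were called in both, and all 1226 had the same sign: 758 higher and 468 lower, where independent lists would share 83.2 and 42.6. The 2 comparisons share no library, but both used 1 estimate of each gene's spread from all 16 libraries. Genes with a low estimated spread are more readily called in both, so the numbers for independent lists are no strict baseline. Across all tested genes the log2 fold changes had a Pearson correlation of 0.822 and a Spearman correlation of 0.807, and genes are not independent replicates. The interaction test found no gene whose diet effect differed between genotypes (0 by edgeR, with 187 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom). Genes called in 1 genotype alone, such as Itgad or Duox2, were therefore not shown to differ between genotypes. All chow animals carried codes 168 to 234 and all HFD animals codes 93 to 161, so any difference between these animal series falls together with diet.

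**Figure D3:**
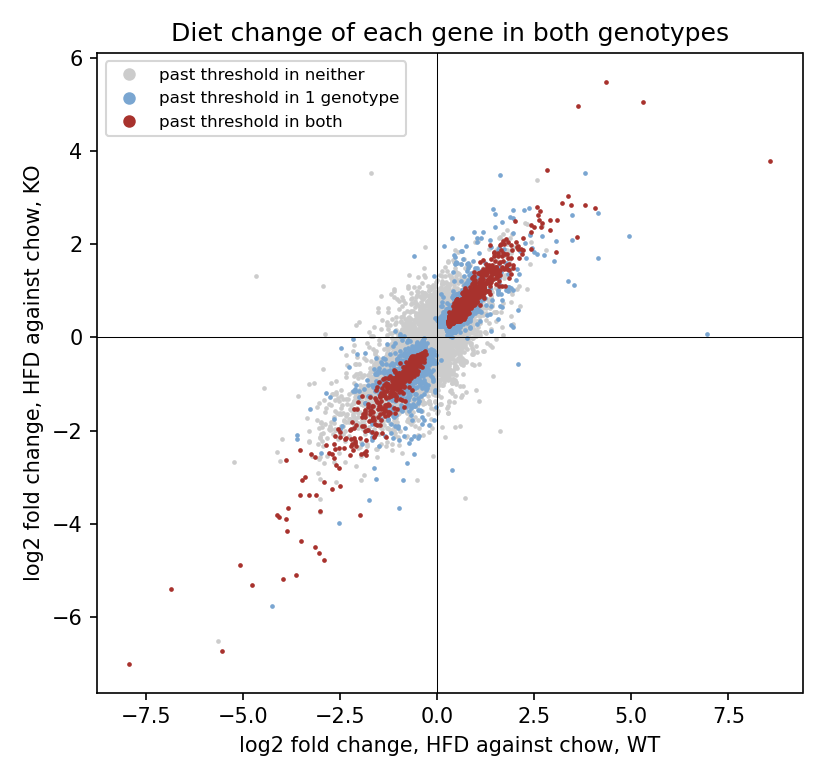
Log2 fold change of HFD against chow for each of 16549 genes in WT (horizontal) and KO animals (vertical), coloured by the number of genotypes in which it passed the threshold. The 1226 genes past it in both lie in the lower left and upper right.

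**Figure D4:**
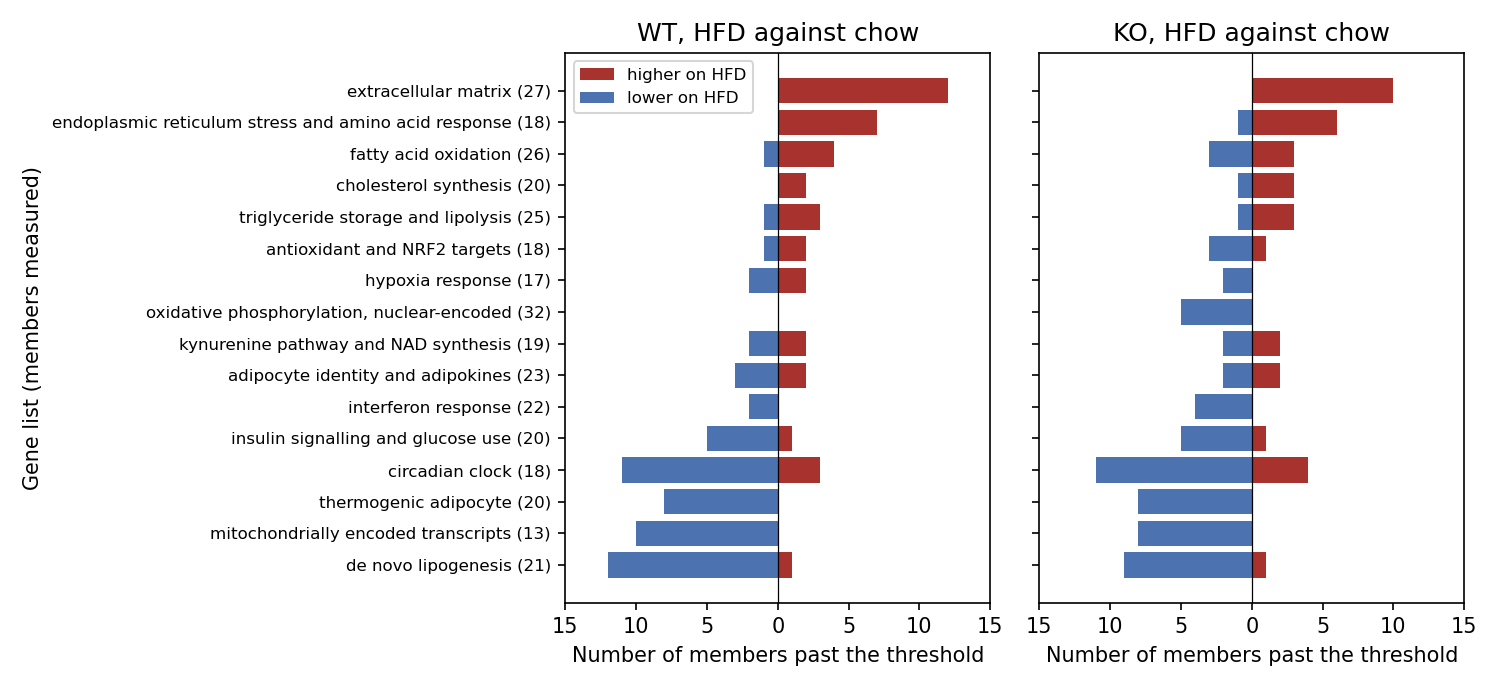
Number of members of each fixed gene list that passed the threshold as higher (right) or lower (left) on HFD, in WT (left panel) and KO (right panel), for lists with at least 4 called members in a genotype. De novo lipogenesis has 12 lower members in WT and 9 in KO, and extracellular matrix 12 and 10 higher members.

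The region around Kmo was examined because a knockout allele can carry flanking DNA of another strain. Of 191 tested genes within 10 Mb of Kmo, 1 was called over both diets, Kmo itself, and 0 of 16358 were called elsewhere by edgeR. Because the window is centred on Kmo, Fisher's test of called genes is fixed by its size and is not given. Without Kmo, 0 of 190 were called by edgeR in the window; at an unadjusted p under 0.05 there were 5 of 190 within and 159 elsewhere. Nnt, whose loss marks some substrains, had 0 to 10 counts in each of the 16 libraries and was too low to be tested.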

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

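The tests of splits, lymphoid content, interval width and clock genes had their readings set after the results were seen. In 124 series of 4 groups each, the gap of a library to the nearest of the other 3 was divided by the group's range. A library was listed when this ratio was above Dixon's 95% critical value for 4 values. This named 51 of 496 groups, where chance gives about 24.8 for independent, normally distributed series. The series share genes, and some hold libraries without a count, so the excess does not measure how many libraries stand apart. KO HFD replicate 1 made up 13 of the 51. Its lymphoid score was 4.51 against −0.05 to 0.28 in the other KO HFD libraries, with T cell genes at 3.53, B cell genes at 5.53, Tcf7 at 4.75, aryl hydrocarbon receptor targets at 1.71, epithelium at 1.43, Cyp1a1 at −1.55, Mlana at −0.14 and Atp4b at −2.32, all higher (log2 CPM). Triglyceride storage (9.17), cholesterol synthesis (5.15), Col6a2 (9.21) and Xaf1 (3.82) were lower there. The Atp4b value rests on 1 count.

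KO chow replicate 4 stood apart in 8 groups: Saa3 (3.82), Slc3a2 (6.94), Acaa1b (5.75), Gpr50 (−1.18), Ina (−0.29) and smooth muscle genes (5.28) were higher, and Slc27a2 (−1.40) and Cyp2f2 (5.68) lower. WT HFD replicate 4 stood apart in 7: Ubd (5.19), Lep (12), Dpp7 (4.76), Arl14epl (−0.98), Chrm4 (−1.39) and Dsg1b (−1.39) were lower and Capn11 (−1.97) higher, since it held both Capn11 counts of its group. WT chow replicate 3 had high Fosb (5.45), Acaa1b (5.61), Arl14epl (−1.34) and Rnase2a (−1.11) and low Ppara (3.52). WT chow replicate 2 had high C1qb (7.84) and Csf1r (7.81) and no Hpcal4 count (−2.95). KO chow replicate 2 had the highest Kmo of its group (0.543 CPM), high insulin signalling genes (7.29) and no Chrm4 count (−2.95). Further single values were the clock score (−2.94) and Cacng5 (−2.38) of KO chow replicate 1, Slc2a5 (5.39) and Sparc (10.86) of WT chow replicate 4, Csf1r (6.81) and Elovl6 (4.68) of WT HFD replicate 1, and Acox2 (−2.33) and Fer1l6 (−2.95) of KO HFD replicate 4. The last were Ripply3 (1.10) of WT chow replicate 1, erythrocyte genes (2.38) of KO chow replicate 3, Tcf7 (3.58) of WT HFD replicate 2 and smooth muscle genes (5.26) of KO HFD replicate 3.

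By camera 7 lists differed in their KO effect between diets: fatty acid oxidation (adjusted p 1.93e-06), interferon response (4.50e-05), de novo lipogenesis (3.12e-04), oxidative phosphorylation (3.18e-04), immediate early genes (7.19e-04), erythrocyte genes (0.00740) and mitochondrially encoded transcripts (0.0478). The adjusted p was 0.797 for each with an estimated correlation.

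Other splits of the same libraries were counted for each result. For diet genes 1 of 35 splits, the real one, gave as many in WT (1957, highest other 3) and 1 of 35 in KO (2071, highest other 344). This is the smallest share that 35 splits can give, so chance was excluded at the limit of 0.05 and no further. By unadjusted p under 0.05 (edgeR) the highest other split had 3168 genes in WT against 4867. In KO it had 4674 against 4951. Over both diets 4 of 100 drawn splits gave 1 or more genes, a share under 0.05 by 1 split (real 1, highest other 1693). The sampling error of 100 drawn splits spans that limit, so chance was not firmly excluded for the count. Kmo was called in no other split. It was not excluded for the count on chow (5 of 35, real 1, highest other 1263) or on HFD (2 of 35, real 1, highest other 1). For the interaction the real count was 0 by edgeR, so all 100 of 100 splits gave as many by construction and the count says nothing (187 genes at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, highest other 2156). The chow split with 1263 genes set WT chow replicates 1 and 3 with KO chow replicates 2 and 4 against the rest; these 4 have the lowest lymphoid scores on chow, which points to a structure of the samples. Of 3 joint splits with this chow grouping, the genes called were 0, 1693 and 0 over both diets and 0, 0 and 2156 in the interaction. For list calls chance was excluded nowhere: 32 of 35 splits on chow (real 9, highest other 21), 12 of 35 on HFD (13, 19), 24 of 35 in WT (12, 20), 24 of 35 in KO (12, 20), 95 of 100 in the interaction (7, 22) and 47 of 100 over both diets (13, 19).

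Only 165 genes had an unadjusted p under 0.05 between genotypes over both diets, fewer than the share of 0.05 that chance alone gives. A balance of lymphoid RNA between the genotypes may contribute: over the 34 other chow splits the difference in mean lymphoid score followed the number of such genes (Spearman rho 0.601, and 0.460 on HFD), and the real difference was 0.323. Among the 17 other chow splits with the smaller score differences, the median was 628 such genes (lowest 140), against 166 in the real split. On HFD the median was 345 (lowest 92), against 188. These splits had score differences up to about the median of the other splits, 1.20 on chow and 0.557 on HFD. The real differences were 0.323 and 0.0706, so some of these splits were less balanced than the real one. Their lowest counts lay below the real counts. Whether balance as close as the real one accounts for the low count therefore cannot be told from them. A linear trend with lymphoid content as the whole cause is argued against, since the share was 1.44% with the lymphoid score as a covariate. Genotype effects below the median interval half-width of 0.31 cannot be told apart from none, because the tests could not detect them in most genes. Larger effects could be missed too: of simulated 1.5-fold changes (0.585 on the log2 scale), 12% were recovered on chow and 12% on HFD.

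Clock genes moved with diet in both genotypes, Dbp by −2.92 in WT and −3.09 in KO and Arntl by 2.57 and 2.80. Lymphoid and muscle RNA are argued against as the cause: with both scores as covariates 14 of 18 clock genes were called in WT and 13 in KO. A different time of collection and the diet itself cannot be told apart, since animal codes fall together with diet and no times were given. Within the 8 HFD libraries animal code and clock score had a Spearman rho of 0.29 (exact p 0.501). Every HFD score lay above every chow score (lowest −2.24 against highest −2.94), but replicate 1 of WT HFD and of KO HFD (−1.84) lay far below the other HFD libraries (0.35 to 1.16). These 2 carry the lowest animal codes of the HFD libraries (93 and 100, the others 120 to 161), a pattern noticed after the values were seen that may point to collection date.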

How the results depend on the processing

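The lane, both-scores and low-lymphoid settings were chosen after the results were seen. With relative log expression or upper-quartile factors, no called list and none of the called genes named in the text reversed; the other called genes were not followed one by one, and with upper-quartile factors 1717 of the 1957 WT and 1785 of the 2071 KO diet calls were shared. Kmo stayed lower in KO in every setting (log2 fold change −3.82 to −5.99 on chow, −5.20 to −6.54 on HFD), but its call was often lost. Calls of KO against WT went from 1 to 0 on chow and on HFD with limma-voom, with no filter, with the 8 libraries of a comparison, with the single-lane term, in merged libraries and with lymphoid scores under 4. Over both diets they went to 0 with limma-voom and in merged libraries. No filter tests more genes and 3 of these settings use fewer samples; for the others the cause was not tested. Without single libraries the counts were 0 to 1 on chow and HFD, 1 over both diets and 0 in the interaction.

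Diet calls in WT (1957) and KO (2071) were 612 and 603 with a log2 fold change of at least 1, 3366 and 3460 at a threshold of 0.10, 1245 and 1284 with no filter, and 625 and 768 with lymphoid scores under 4. In WT they were 1140 from 8 libraries and 225 in merged libraries, which leave 2 WT HFD libraries; in KO 3412 with limma-voom. Leaving out single libraries gave 689 to 2400 in WT and 745 to 2714 in KO. The replicate block gave 1050 and 1126. Of 24 pairs of libraries with the same replicate number, 9 correlated above 0.1 (range −0.693 to 0.553). The first principal component correlated with the lymphoid score (r −0.935), so these correlations cannot decide whether replicate numbers pair the animals.

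List calls on chow, on HFD, in WT, in KO, in the interaction and over both diets (9, 13, 12, 12, 7 and 13) were all 0 with an estimated correlation, and 0, 0, 6, 7, 0 and 0 with fry. On HFD both scores and the single-lane term each gave 7, and over both diets both scores gave 5. The interaction had 11 with the replicate block, 13 in merged libraries and 12 with lymphoid scores under 4. Without single libraries the ranges were 8 to 13, 9 to 16, 10 to 14, 10 to 14, 6 to 18 and 5 to 20. Lists were not run with DESeq2.

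Directions of lists in KO against WT turned in some settings; a turn was counted where camera changed direction and called the list before or after it. Mean log2 fold changes follow, and the cause was not tested. In merged libraries, on chow, macrophage genes had 0.273 and adipose progenitor genes 0.269; on HFD, oxidative phosphorylation 0.187, fatty acid oxidation 0.220, T cell −2.40 and endoplasmic reticulum stress −0.0143. There the interaction had oxidative phosphorylation 0.103, fatty acid oxidation 0.0410, T cell −2.28 and B cell −3.84, and over both diets macrophage genes had 1.56e-04 and extracellular matrix −0.0228. With the muscle score, extracellular matrix had 0.0269 on HFD and 0.00240 over both diets, skeletal muscle 0.0678 on HFD and smooth muscle 0.111 over both diets. With both scores extracellular matrix had −0.00539 on HFD and −0.0243 over both diets, and skeletal muscle 0.0472 on HFD. A skeletal muscle list corrected for its own score moves toward 0 by construction. T cell genes had 0.129 with the surrogate variable and 0.118 with the lymphoid score on chow, and with limma-voom −0.961 on HFD and −1.03 in the interaction. With lymphoid scores under 4, T cell genes had −0.459 on HFD, mitochondrially encoded −0.0150 and interferon genes 0.0374 in the interaction, and cell cycle 0.138 over both diets. HFD against chow in KO turned for epithelium with no filter (−1.45).

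Leaving out single libraries gave these ranges on chow: oxidative phosphorylation −0.0290 (without KO chow replicate 2) to 0.236, de novo lipogenesis −0.260 to 0.0602 (KO chow replicate 4), cholesterol synthesis −0.227 to 0.138 (WT chow replicate 3), macrophage −0.464 to 0.273 (WT chow replicate 2), T cell −1.34 to 0.768 (WT chow replicate 4), adipose progenitor −0.414 to 0.270 (WT chow replicate 2), smooth muscle −0.276 (KO chow replicate 4) to 0.177, skeletal muscle −1.84 to 0.575 and immediate early −0.887 to 0.0675 (both WT chow replicate 3). On HFD they were oxidative phosphorylation −0.0673 to 0.0737 (WT HFD replicate 4), fatty acid oxidation −0.0624 to 0.0817 (KO HFD replicate 1), inflammatory −0.468 to 0.0476 and B cell −3.31 to 3.11 (both WT HFD replicate 2), T cell −1.74 (KO HFD replicate 1) to 1.74, endothelial −0.131 (KO HFD replicate 3) to 0.10 and cell cycle −0.264 (WT HFD replicate 4) to 0.110. In the interaction they were oxidative phosphorylation −0.246 to 0.0153 (KO chow replicate 2), T cell −1.50 to 1.97 and B cell −3.04 to 3.37 (both turned without KO HFD replicate 1). Over both diets they were oxidative phosphorylation −0.0214 (KO chow replicate 2) to 0.114, cholesterol synthesis −0.0926 to 0.0899 and immediate early −0.346 to 0.135 (both WT chow replicate 3), T cell −0.983 to 0.752 and B cell −1.79 to 1.42 (both WT HFD replicate 2; T cell also without WT chow replicate 4, 0.607).

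Within 5 and 20 Mb of Kmo, as within 10 Mb, no gene but Kmo was called by edgeR over both diets, on chow or on HFD. Genes such as Cacng5 or Atp4b with few counts are the ones whose fold changes depth limits.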

Other observations

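The tests of Kmo against list scores, the flanking-gene test without Kmo and the genes of this part were chosen after the results were seen. Of the imprinted genes looked at, 3 were higher on HFD: Peg3 by 2.90 in WT and 2.51 in KO (edgeR adjusted p = 0.00175 and 0.00389), Zim1 by 3.45 and 2.85 and Mest by 3.22 and 2.89 (edgeR adjusted p = 0.0226 and 0.0311). Plagl1 (0.59 and 0.98), H19 (0.18 and −0.01) and Dlk1, which was lower on HFD (−1.05 and −0.62), did not pass. Ighm stood at 858 to 1539 CPM in the 8 HFD libraries and 314 to 759 in the 8 chow libraries, and did not track the B cell gene Cd79a. Of the genes flanking Kmo, Opn3 was lower in KO over both diets by −0.45 (edgeR quasi-likelihood test, unadjusted p = 0.00876) and Chml by −0.29 (edgeR, unadjusted p = 0.0274), neither past the threshold (edgeR adjusted p = 1); the 2 genes overlap, and counts without strand do not separate them. Without Kmo, 5 of 190 genes within 10 Mb had an unadjusted p under 0.05 over both diets (Fisher's exact test, p = 0.0409). On chow it was 3 of 190 (p = 0.442) and on HFD 5 of 190 (p = 0.0647), within 20 Mb p was 0.0422 over both diets, 0.567 on chow and 0.419 on HFD, and within 5 Mb 0.0268, 0.315 and 0.0404 (each Fisher's exact test). The 5 genes over both diets include Opn3 and Chml, although Fisher's test takes genes as independent. These p-values were not adjusted over windows and comparisons, so an excess near Kmo was not established.

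Kmo followed the lymphoid score across the 8 WT libraries (r 0.919, permutation p 0.00310, rho 0.857, permutation p 0.0107, r 0.826 without the 2 farthest libraries). Here and for the lists below, libraries were permuted without regard to diet. Mean Kmo was 11 CPM in WT chow and 6.66 in WT HFD, and the mean lymphoid score 3.08 and 1.31. A difference between diets is therefore not separated from a relation within a diet. Among 30 lists, B cell genes (r 0.936, rho 0.833, permutation p 0.00231, BH 0.0346, r 0.877 without the 2 farthest) and triglyceride storage (r −0.925, rho −1, permutation p 7.44e-04, BH 0.0223, r −0.951 without the 2 farthest) passed. The triglyceride storage list shares members such as Plin1 and Fabp4 with the adipocyte identity list, so it too bears on the share of adipocyte RNA. Lymphoid cells as the sole source are argued against by a slope of 0.449 (0.257 to 0.641), under the 1 that proportion needs. A lower share of adipocyte RNA stays open: adipocyte identity genes (r −0.865, rho −0.881, permutation p 0.00903, BH 0.0677, r −0.724 without the 2 farthest) and endothelial genes (r −0.760, rho −0.833, permutation p 0.0379, BH 0.190, r −0.507 without the 2 farthest) both ran opposite to Kmo, and neither passed. So did smooth muscle genes (r −0.773, rho −0.810, permutation p 0.0351, BH 0.190, r −0.543 without the 2 farthest) and skeletal muscle genes (r −0.633, rho −0.667, permutation p 0.101, BH 0.434, r −0.670 without the 2 farthest), where a lower adipocyte share alone would raise other cell types; neither passed. Macrophages as a source stay open as well (r 0.490, rho 0.619, permutation p 0.207, BH 0.443, r 0.146 without the 2 farthest).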
